A study of Mus musculus with 11 samples.

How the data were processed

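Cap analysis of gene expression (CAGE) was made from total RNA of the whole hippocampus of C57BL/6N male mice, with cap-trapped and random-primed libraries. There was 1 library for naive mice and 1 for each side of the brain in 5 photothrombosis (PT) conditions, 11 in all. The deposited table holds CPM (reads scaled to the library total) per gene, and every value was a whole number of reads (within 0.0001) of its library's total. Per the submitters' processing notes, BWA 0.7.17, HISAT2 2.0.5, DESeq2 1.20.0 and the genome build GRCm38 were used. Their roles, the annotation release, the rule that gave reads to genes, and the origin of the reads outside the listed genes are not given in the sources used here. The raw reads were not analysed here.

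Library totals, recovered from the step between CPM values, were 14003626 reads for naive, 17501789 and 16053691 for PT 7 d (infarcted, then non-infarcted side), and 19222979 and 17696949 for PT 7 d with levetiracetam (LEV). They were 13382623 and 13940220 for PT 1 m, 15889269 and 22377376 for PT 1 m LEV, and 18349813 and 16857014 for PT 2 m after LEV withdrawal. A count of 0 allows up to 3 reads, which is 0.134 to 0.224 CPM. Intervals for single libraries are exact Poisson bounds at 95%. Floors and intervals cover counting error only, and whether duplicate reads were removed is not given in the sources used here.

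The table holds 22377 genes, of which 109 were at 0 in all libraries, and 16057 with a mean of at least 1 CPM were tested. Their Ensembl identifiers were matched to GENCODE M21 for coordinates, length and type, where 22335 matched without and 21747 with the version number. A symbol shared with another gene was found for 40 genes, and 626 genes had the same reads in every library as another gene (over 110 reads in all), so that such genes cannot be separated. Values were used as log2(CPM + 1).

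All tests used limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The infarcted side was compared with the other side over the 10 PT libraries with condition as a block (4 residual degrees of freedom). LEV against no LEV, and 1 m against 7 d, were fitted together on 4 condition means (7 d, 7 d LEV, 1 m, 1 m LEV). Sides were averaged first, since they may share animals, which left 1 residual degree of freedom and a prior of 21.6 degrees of freedom. The difference between sides was tested for time and for LEV over the same 4 conditions (2 residual degrees of freedom). Comparisons with naive, and of withdrawal with PT 1 m LEV, had no test, and a gene was counted when it differed by a log2 of at least 1 in the same direction on both sides. Pearson's r and Spearman's rho across genes set the PT change from naive on 1 side against the LEV change on the other side.

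There were 28 gene lists with 407 members, 369 of them tested. They cover GABA-A receptor subunits; GABA synthesis, transport, chloride and GABA-B; ionotropic glutamate receptors; metabotropic glutamate receptors and glutamate transport; and SV2 and vesicle release. Others are voltage-gated channels, immediate early genes, reactive astrocytes, microglia, activated microglia and phagocytes, interferon response, myelinating oligodendrocytes, oligodendrocyte precursors, endothelium, and pericytes with smooth muscle and meningeal fibroblasts. The rest are choroid plexus, blood cells, neighbouring neocortex, thalamus and striatum, dentate granule cells, CA1 and CA2 with CA3 pyramidal cells, interneurons, neurogenesis, ependyma and cilia, heat shock and unfolded protein response, glucocorticoid response, cholesterol synthesis and the mitochondrial respiratory chain. Camera tested each list against the other genes with a preset correlation of 0.01, adjusted over the 28 lists, beside camera with an estimated correlation and fry. Fry tests whether a list's genes move, on balance, 1 way, and does not compare them with other genes. Against naive, a list's median was placed among 10000 random lists matched on mean expression.

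The tests, the lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where the text says otherwise. The adjustment of members over their list alone was not part of that plan. It does not correct for the number of lists or contrasts, and members of a list may move together. In each tested contrast, the named genes were up to 10 per direction with the largest change among those past the threshold with the same sign in every pair. Remaining places went to the smallest p among genes with the same sign in every pair and a mean of at least 5 CPM, stated as not passing. Against naive, up to 10 per direction were named by the smaller of the changes on both sides, and the same was done for withdrawal. Sv2a, Gfap, the GABA-A receptor subunits and up to 4 members of each passing list were named too. Genes known only by an identifier or a clone name were counted but not named, and some genes that the rule picks are not named here.

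The steps were tested on simulated data with the same depths. Each gene's spread came from the 10 PT libraries with condition and side fitted, and each library was drawn on its own. Differences between animals of different conditions, or between batches, were not simulated beyond that spread. The real error of the LEV and time fits may therefore be larger. Of genes moved by a log2 of 1, the side fit called 96.8%, the LEV fit 98.3%, the time fit 95.9%, and the tests on side differences 72.7% (time) and 64.7% (LEV). At a log2 of 0.5 these were 71.2%, 87.5%, 79.1%, 15.9% and 10.6%. Unchanged genes made up 9.18% of the calls for side, 20.7% for LEV, 27.4% for time, 12.4% for the side difference by time and 10.1% for that by LEV, all above the nominal 5%. Camera with the preset correlation called 2 of 2 moved lists in each of the 3 fits but also 2 of 28 lists in each unchanged set. The estimated correlation and fry called 2 of 2 moved lists for side and 0 for LEV and time. The count against naive found 183 of 200 genes moved by a log2 of 2, and 7 genes in unchanged data.

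The alternatives were a pseudocount of 0.25 or 5, no filter or a mean of at least 5 CPM, TMM scaling (edgeR 4.0.16) or quantile normalization, eBayes without a trend, and edgeR or DESeq2 1.42.0 on whole reads. Further ones were each condition or library left out in turn, no block, 8 libraries as independent or with duplicateCorrelation, and each side on its own. Removal of a trend on GC content and gene length (mgcv 1.9.3) and leaving out 2 libraries low in choroid plexus genes were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the series, and naive was left out of the tests because it has 1 library and no side.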

Results

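The libraries were made by cap analysis of gene expression (CAGE), which sequences the capped 5′ ends of transcripts, from total RNA of the whole hippocampus of C57BL/6N male mice. In the photothrombosis model (PT), the dye rose bengal (35 mg/kg) and 30 min of LED light (565 nm) over a circle of 3.5 mm clot the vessels of the left parietal cortex. Levetiracetam (LEV), an anti-seizure drug that binds the synaptic vesicle protein SV2A, was given in the drinking water at 5 mg/mL. The series text has LEV begin 1 month after PT, so when the PT 7 d LEV animals received it is not given. There were 11 libraries in 11 groups of 1. They were 1 naive library and, for each of 5 PT conditions, 1 library from the infarcted and 1 from the non-infarcted side. The conditions were PT 7 d, PT 7 d LEV, PT 1 m, PT 1 m LEV and PT 2 m after LEV withdrawal. Library totals ranged from 13382623 to 22377376 reads, of which 93.01% to 96.08% fell in the listed genes. With 1 library per group there were no replicates within a group. The tests therefore compared sides over conditions, or conditions over sides and the other factor. All values are in CPM (reads of a gene scaled to the library total) and log2 differences are of CPM + 1. The labels do not say whether both sides came from the same animals, how many animals a library held, or which of the 2 ages named for the series (8 to 10 and 65 to 85 weeks) a library came from.

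The first comparison asked how the hippocampus on the infarcted side differed from the other side. Genes of microglia, astrocytes and the interferon response stood higher on the infarcted side, most at PT 7 d. In PT 7 d the median log2 difference between sides was 1.69 over 14 genes of activated microglia and phagocytes. It was 1.11 over 16 microglia genes, 0.70 over 14 reactive astrocyte genes and 0.65 over 12 interferon response genes. In PT 7 d LEV these medians were 0.60, 0.45, 0.59 and 0.56, and in PT 1 m they were 0.05, 0.15, 0.26 and -0.22. In PT 1 m LEV they were 0.27, 0.20, 0.18 and 0.35, and at PT 2 m 0.26, 0.10, 0.20 and 0.08. Among single genes in PT 7 d, the log2 difference was 2.97 for Spp1, the matrix protein osteopontin, and 2.89 for Lyz2, a lysozyme of phagocytes. It was 2.77 for Lgals3, a galectin of phagocytes, 1.65 for Trem2, a lipid receptor of microglia, and 2.46 for Lcn2, an iron-carrier protein of reactive astrocytes. In PT 1 m the same genes gave -0.48, 0.11, 0.30, 0.13 and 2.02.

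Over the 5 pairs of libraries, the microglia list had 16 of 16 members above 0 (median 0.41) and the activated microglia list 14 of 14 (median 0.56). The reactive astrocyte list had 14 of 14 members above 0 (median 0.37) and the interferon list 11 of 12 (median 0.41). By limma, 0 members passed with adjustment over all genes. Adjusted over the list alone, which was not planned and does not correct for the number of lists, more members passed. These were 13 members of the microglia, 12 of the activated microglia, 7 of the astrocyte and 7 of the interferon list, all higher. All 4 lists passed camera with a preset correlation (adjusted p = 3.99e-13, 3.99e-13, 2.14e-10 and 4.53e-06 in the order microglia, activated microglia, astrocyte, interferon). None passed otherwise: adjusted p = 0.417, 0.417, 0.397 and 0.417 with an estimated correlation, and fry gave 0.421 for each. Gfap (ENSMUSG00000020932.14, GRCm38 chromosome 11, 102887336 to 102900912), the intermediate filament of astrocytes, stood at 462 ± 141 CPM (SD, n = 5) on the infarcted and 320.3 ± 77.8 CPM on the other side. Its log2 difference of 0.51 (SE 0.09) was above 0 in 5 of 5 pairs but did not pass (limma adjusted p = 0.248). Naive Gfap was 276.9 CPM.

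**Figure D1:**
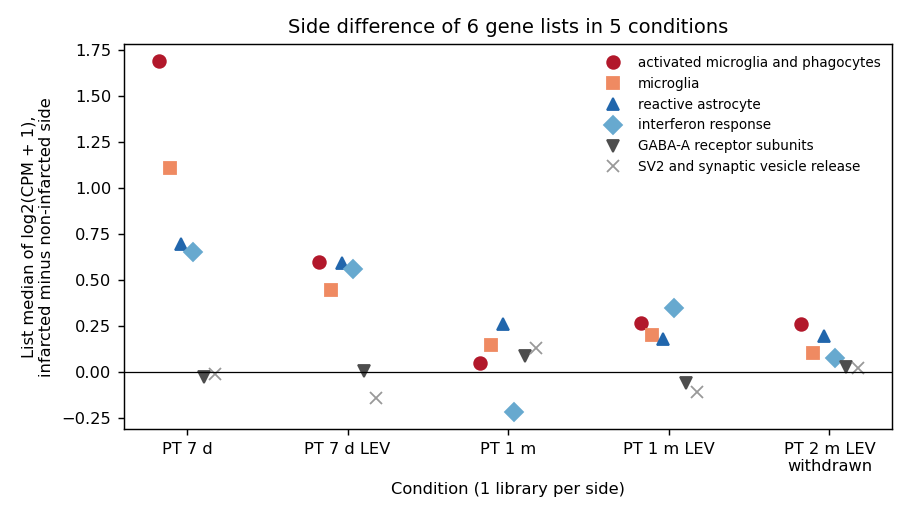
Median log2(CPM + 1) difference between the infarcted and the non-infarcted side (y axis) of 6 gene lists in each of the 5 conditions (x axis), 1 library per side, so that no error can be drawn. Activated microglia genes run from 1.69 in PT 7 d to 0.05 in PT 1 m, while the GABA-A receptor and synaptic vesicle lists lie between -0.14 and 0.13.

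The genes with the smallest p that were higher in 5 of 5 pairs were Lgals3bp, a secreted galectin-binding protein (0.61, SE 0.09), and Gltp, a glycolipid transfer protein (0.33). They also held Lamp2, a lysosomal membrane protein (0.33), Csf1r, the growth factor receptor of microglia (0.34), C4b of the complement system (0.53), Tgfbr2, a TGF-beta receptor (0.39), Fabp7, a fatty acid carrier of astrocytes (0.38), Vim, the filament vimentin (0.74), and Thbs4, a thrombospondin (0.62). Lower in 5 of 5 pairs were Neurod6, a transcription factor of pyramidal neurons (-0.30), Spink8 (-0.32), Rasd1 (-0.27), Prmt5 (-0.20), Kcnab2, a potassium channel subunit (-0.20), Gorab (-0.27), Rnf41 (-0.17), Dynlt3 (-0.17), Zfp846 (-0.25) and a second entry named Arhgef4 (-0.16). None of these passed, with adjusted p from 0.233 upward by limma. Sv2a, which encodes the target of LEV, differed by -0.03 (SE 0.06; -0.07 to 0.04 over the alternatives) between sides, at 139 and 142 CPM. The 13 measured GABA-A receptor subunits ranged from -0.20 for Gabrr2 (-0.43 to -0.07 over the alternatives) to 0.08 for Gabra3 (-0.02 to 0.17), with 0 passing.

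Of the other 24 lists, 5 passed camera with the preset correlation and none with an estimated one. Higher were markers of neighbouring neocortex, thalamus and striatum (median 0.14, 13 of 16 members above 0). Prkcd stood at 0.29. Adjusted over the list alone 2 members passed, and the list test gave adjusted p = 0.00634, or 0.395 with an estimated correlation. Ependyma and cilia genes (median 0.13, 10 of 10 above 0) gave adjusted p = 0.00279, or 0.395 with an estimated correlation. Myelinating oligodendrocyte genes (median 0.08, 10 of 13 above 0) gave 0.00706 and 0.734, and this call also ended without the PT 7 d pair, left out after the data were seen. Lower were activity-induced immediate early genes (median -0.04, 15 of 21 below 0; 0.00706 and 0.395) and interneuron genes (median -0.05, 11 of 15 below 0; 0.0202 and 0.734), among which Pvalb, the parvalbumin of fast-spiking cells, stood at -0.26.

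Over all 16057 tested genes, limma called 0 genes between sides, with 1221 genes at an unadjusted p under 0.05 (963 higher and 258 lower), where 803 would fall by chance. EdgeR also called 0 (1264 at an unadjusted p under 0.05) and DESeq2 14 (10 higher, 4 lower). Without the PT 1 m pair limma called 50, all higher, and without any other pair 0.

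The second comparison asked what LEV changed after PT, at 7 d and at 1 m. Dpysl2 (ENSMUSG00000022048.8, chromosome 14, 66802864 to 66868688), a microtubule-binding protein of axon growth, rose with LEV. It stood at 217 ± 16.1 CPM (SD, n = 4 libraries) with LEV and 131 ± 9.82 CPM without, 1.64-fold (log2 0.72, SE 0.12), and was higher in 4 of 4 matched pairs. Naive Dpysl2 was 125.4 CPM, and after withdrawal it stood at 161 CPM on the infarcted and 89.0 CPM on the other side. Hbb-bs (ENSMUSG00000052305.6, chromosome 7, 103826534 to 103828096), the adult beta-globin chain of red blood cells, fell to 19.8 ± 11.4 from 37.2 ± 8.42 CPM (log2 -1.02, SE 0.16), lower in 4 of 4 pairs. Naive Hbb-bs was 91.0 CPM, and the neighbouring globin gene Hbb-bt, at -0.54 (-0.69 to -0.33 over the alternatives), did not pass (adjusted p = 0.624). The globin level follows the amount of blood in a sample. Limma called these genes with adjusted p = 0.0472 for Dpysl2 and 0.0351 for Hbb-bs. The only other call was Cox8b, a subunit of cytochrome c oxidase, named after its values were seen because it was not higher in every pair. Its log2 change was 0.81 (adjusted p = 0.0472). It stood at 2.17 CPM in PT 1 m infarcted and 25.9 CPM in PT 1 m LEV infarcted, while on the non-infarcted side at 1 m its log2 change was -1.07. At 1 m the libraries stood in the same order for Cox8b as for the choroid plexus gene Ttr, though not at 7 d. Whether uneven choroid plexus tissue lies behind the Cox8b call was not tested.

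Sv2a did not differ detectably with LEV, at 136 ± 11.99 CPM with and 143 ± 9.13 CPM without (log2 -0.08, SE 0.12, adjusted p = 0.951; -0.18 to 0.03 over the alternatives). Among GABA-A receptor subunits, which form the chloride channel of fast inhibition, 10 of 13 lay above 0 (median 0.08). Of them 0 passed over all genes and 1 adjusted over the list alone. Gabra2 stood at 0.20 (4 of 4 pairs; 0.09 to 0.31 over the alternatives). The GABA synthesis and transport list, which holds the GABA-making enzyme gene Gad2 (0.29, 4 of 4 pairs), had a median of 0.15 with 11 of 15 above 0, and 0 passed over the list alone. With the preset correlation camera gave adjusted p = 0.0238 for the GABA-A and 0.0162 for the GABA synthesis list, but both were 0.770 with an estimated correlation. On simulated data the estimated correlation called 0 of 2 moved lists in this fit, and the preset one also called 2 of 28 unchanged lists. Losing a call with the estimated correlation therefore cannot tell a moved list from an unmoved one here.

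Glial lists lay below 0 with LEV. Activated microglia genes had a median of -0.25, with 14 of 14 members below 0 and 3 lower adjusted over the list alone. Microglia genes had a median of -0.16 (15 of 16 below 0; 0 over the list alone), and reactive astrocyte genes -0.14 (12 of 14 below 0; Gfap and Lcn2 lower over the list alone). Gfap stood at 309 ± 66.0 CPM with LEV and 429 ± 173 CPM without (-0.42, lower in 4 of 4 pairs, adjusted p = 0.685). Lcn2 was at -0.92 (adjusted p = 0.0706), with -1.46 and -1.72 on the infarcted and -0.23 and -0.29 on the other side. Over the alternatives Lcn2 ranged from -1.69 to -0.26, passing in 5 of 21, and Gfap from -0.65 to -0.18. Camera with the preset correlation gave adjusted p = 1.23e-07, 0.000273 and 0.00264 for these 3 lists. With an estimated correlation, which found no moved list in this fit on simulated data, each gave 0.770. At 7 d on the infarcted side the log2 change with LEV was -2.36 for Lgals3, -2.39 for Gpnmb and -1.54 for Lyz2, while at 1 m on that side it was 0.07, 0.44 and 0.02.

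A further 7 lists passed with the preset correlation, and each had adjusted p = 0.770 with an estimated correlation, which decides nothing in this fit. Higher were activity-induced immediate early genes (median 0.16, 16 of 21 above 0, preset adjusted p = 0.000649). In these, Npas4, a transcription factor made on neuronal firing, stood at 1.12 on the infarcted and 1.13 on the other side at 1 m, but at 0.17 and -0.08 at 7 d. Interneuron genes (median 0.12; 0.00642) held Cnr1, the cannabinoid receptor, at 1.55 and 1.22 at 1 m and -0.18 and 0.15 at 7 d. Glucocorticoid response genes (0.09; 0.0238) held the metallothionein Mt2 at 1.44 and 1.58 at 1 m and -0.07 and 0.52 at 7 d, with 4 members higher and 1 lower over the list alone. Cholesterol synthesis genes (0.08; 0.0324) and choroid plexus genes (0.27; 1.1e-05) were the others, the last with 4 members higher over the list alone but with Ttr at 5.52 and -4.07 on the 2 sides at 1 m. Lower were dentate granule cell genes (-0.21, 8 of 9 below 0; 0.00108), with C1ql2 at -0.30, and blood cell genes (-0.23; 0.00858), of which 4 were measured, 2 globin genes below 0 and S100a8 and S100a9 above, with pair medians below 0 at 7 d and above 0 at 1 m. Of the 12 LEV list calls, those of GABA-A, reactive astrocyte, microglia, interneuron, glucocorticoid and cholesterol genes also ended without PT 1 m infarcted and PT 1 m LEV non-infarcted, 2 libraries low in choroid plexus genes left out after the data were seen. Blood and glucocorticoid calls ended with TMM scaling, and reactive astrocyte, choroid plexus, blood and glucocorticoid calls with 8 libraries as independent.

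Other genes that moved 1 way in 4 of 4 pairs without passing were, higher, Ndufs5-ps (0.61, adjusted p = 0.145), Ust (0.49), Sec22c (0.50), Epas1 (0.43), Sgk1 (0.43), Cdr2 (0.52), Pde7b (0.45), Herc3 (0.51) and Ppp1r3f (0.49). Lower were Chil1 (-0.54), Srsf3 (-0.54), Hpgd (-0.54), Snrnp35 (-0.50), Zfp36l1 (-0.48), Msn (-0.51), Gp1bb (-0.54) and Plekhm1 (-0.47). Over the alternatives Cdr2 ranged from 0.17 to 0.87, Ppp1r3f from 0.25 to 0.72 and Chil1 from -0.75 to -0.32. Some moved mostly at 1 m. Herc3 stood at 0.17 and 0.04 at 7 d (infarcted, then other side) but at 1.00 and 0.85 at 1 m. Srsf3 stood at -0.10 and -0.22, then at -1.15 and -0.69, and Zfp36l1 and Gp1bb moved likewise. Others were alike at both times, such as Epas1 (0.41 and 0.39, then 0.55 and 0.39) and Hpgd (-0.50 and -0.54, then -0.62 and -0.48). This fit had 1 residual degree of freedom, so nearly all of each gene's spread was borrowed from other genes. On simulated data, which held no added spread between conditions, 20.7% of the calls of this fit were unchanged genes. The count of 3 was 0 with TMM or quantile scaling, a pseudocount of 5, no filter or no trend, 7 with edgeR and 1 with DESeq2. It was 0 without PT 7 d non-infarcted, PT 7 d LEV non-infarcted, PT 1 m infarcted or PT 1 m non-infarcted. It was 62 without PT 7 d infarcted and 7 without PT 7 d LEV infarcted. Dpysl2 passed in 10 of 22 alternatives (adjusted p from 0.000149 to 0.925) and Hbb-bs in 8 of 22 (9.89e-09 to 0.925).

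**Figure D2:**
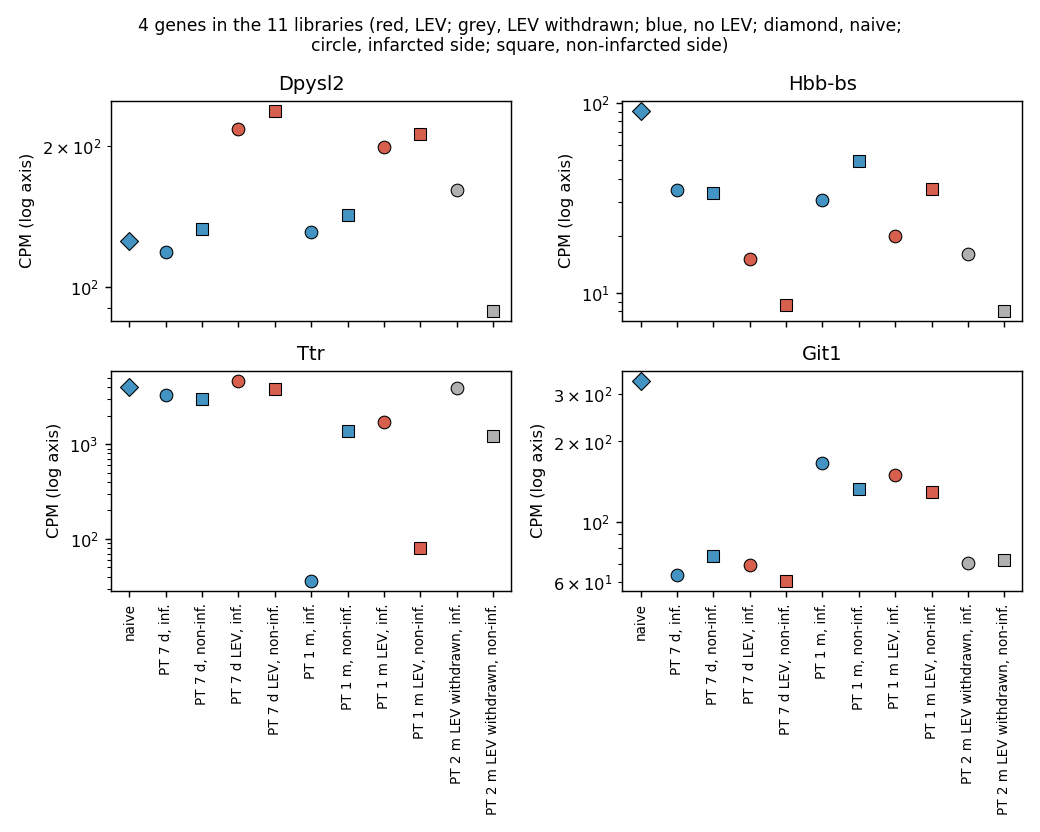
CPM (y axis, log scale) of Dpysl2, Hbb-bs, Ttr and Git1 in each of the 11 libraries (x axis, 1 point per library). Dpysl2 was at 217 ± 16.1 CPM in the 4 LEV libraries against 131 ± 9.82 CPM in the 4 without, and Git1 was at 337 CPM in the naive library and 60.5 to 74.5 CPM in the 7 d libraries.

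The third comparison asked how 1 m after PT differed from 7 d. A batch that parts the naive and 1 m libraries from the 7 d and 2 m libraries may lie behind much of the difference, as described further below. Of the 28 lists, choroid plexus genes had the lowest median: 12 of 12 members fell (-2.06). Ttr (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321), the thyroid hormone carrier of the choroid plexus, was at 799.6 ± 867 CPM at 1 m and 3689 ± 713 CPM at 7 d (SD, n = 4 libraries; log2 -3.65, SE 0.15, lower in 4 of 4 pairs). At 1 m it was very uneven between libraries, at 36.2 CPM in PT 1 m infarcted and 1372 CPM in PT 1 m non-infarcted. In PT 1 m LEV it was at 1709 CPM (infarcted) and 80.7 CPM (other side). The SE comes from condition means, and each 1 m mean averaged a low and a high library. It therefore does not measure this spread between libraries. Folr1 (-2.78), Mfrp (-2.71), Clic6 (-2.22), Wfdc2 (-2.17), Kcnj13 (-2.13), F5 (-2.10), Aqp1, a water channel (-2.09), and Ecrg4 (-2.05) fell with Ttr. The same averaging of low and high 1 m libraries entered their fits. Over the alternatives Ttr ranged from -4.95 to -1.25, Folr1 from -3.38 to -1.64, Mfrp from -3.48 to -1.53, Clic6 from -2.72 to -1.32, Wfdc2 from -2.80 to -1.17, Kcnj13 from -2.64 to -1.32, F5 from -2.85 to -0.72, Aqp1 from -2.96 to -0.97 and Ecrg4 from -2.66 to -0.94. F5 was at 0.822 and 1.48 CPM in PT 1 m infarcted and PT 1 m LEV non-infarcted but at 9.25 and 18.9 CPM in the other 1 m libraries. Mmp12, a macrophage elastase, was called lower (-2.12), but it stood at 29.9 CPM in PT 7 d infarcted and at 1.00 to 2.29 CPM in the other 7 d libraries, and ranged from -6.04 to -0.98 over the alternatives.

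Microglial genes fell as well: 10 of 14 activated microglia genes (median -0.66), among them Gpnmb (-1.40) and Lgals3 (-1.39), and 5 of 16 microglia genes, with Itgam, an integrin (-1.03), and Cx3cr1, the fractalkine receptor (-0.68). In the pair with PT 7 d infarcted Gpnmb changed by -3.61 and Lgals3 by -3.16, and in the other 3 pairs by -0.55 to -0.77 and -0.69 to -0.99. Over the alternatives Gpnmb ranged from -2.19 to -0.62, Lgals3 from -2.09 to -0.70 and Itgam from -1.34 to -0.67. Interferon response genes fell in 7 of 12 cases, such as the transcription factor gene Irf7 (-0.78) and Oasl2 (-0.74). In the non-infarcted pair without LEV these stood at -0.24 and -0.09, and over the alternatives Irf7 ranged from -1.09 to -0.45 and Oasl2 from -1.09 to -0.38, each passing in 18 of 22. Ependyma and cilia genes fell in 7 of 10 (Rsph1 -0.98). Genes of the unfolded protein response fell in 5 of 14, with the chaperones Hspa5 (-0.58) and Manf (-0.67), and glucocorticoid response genes in 6 of 13 with 1 higher, among them Sgk1, a kinase (-1.18), and Tsc22d3 (-0.87). Adjusted over the list alone, the lower counts were 12 for choroid plexus, 11 for activated microglia, 7 for microglia, 9 for interferon, 7 for ependyma, 6 for heat shock and 8 for glucocorticoid genes.

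Several genes of inhibition rose, some of them in the pattern of the batch named above. Slc6a11 was at 102.5 CPM in naive and 69.5 to 112.6 CPM at 1 m. It was at 45.2 to 65.1 CPM at 7 d and at 59.5 and 56.3 CPM at 2 m. Gabbr1 and Gabarap parted the same libraries, while Vip at 2 m (11.1 and 8.54 CPM) lay between its 7 d and 1 m values. Of the GABA synthesis and transport list 6 of 15 rose, including the GABA transporter Slc6a11 (0.82, SE 0.13), the GABA-B receptor Gabbr1 (0.55) and both GABA-making enzymes, Gad1 (0.42) and Gad2 (0.42), while Gabarap, which acts in receptor trafficking and autophagy, fell (-0.58). Interneuron genes rose in 5 of 15, with the neuropeptides Vip (1.25) and Cort (0.70), and Reln (0.52). Cnr1 was called too (0.66), but it stood at 1.53 and 1.18 in the LEV pairs and at -0.20 and 0.11 in the others, and it passed in 9 of 23 alternatives. Of the 13 GABA-A subunits 1 passed, higher. CA1 pyramidal cell genes rose in 2 of 7, Pou3f1 (0.69) and Mpped1 (0.59). Adjusted over the list alone, 6 GABA synthesis genes were higher and 1 lower, 6 interneuron genes higher, 1 GABA-A subunit higher and 2 CA1 genes higher and 1 lower. Sv2a (0.04, SE 0.12, adjusted p = 0.850) and Gfap (-0.33, adjusted p = 0.0931) did not pass, with -0.07 to 0.13 and -0.57 to -0.10 over the alternatives. These 10 lists passed camera with the preset correlation (adjusted p from 4.08e-27 for choroid plexus to 0.0348 for CA1), the GABA-A list did not (0.271), and all 10 lost the call (adjusted p = 0.745 with an estimated correlation). On simulated data the estimated correlation called 0 of 2 moved lists in this fit too, so this loss decides nothing. The preset one also called 2 of 28 unchanged lists. The CA1 call also ended with TMM scaling, with 8 libraries as independent and without the 2 libraries low in choroid plexus genes, and the microglia call with 8 libraries as independent.

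Leaving out genes known only by a clone name or identifier, the 10 largest rises with the same sign in 4 of 4 pairs were in Rpl9-ps6 (2.02), Rpl21-ps15 (1.66), Rps21 (1.44), Cox5b-ps (1.62), Atp5e (1.65), the small RNA genes Rny1 (1.90) and Rn7s2 (1.47), the histone gene H3c13 (1.39), Stxbp3, a syntaxin-binding protein of vesicle fusion (1.70), and Cacna1d, a calcium channel (1.46). Rny1 reached 0.19 and 0.01 in the LEV pairs. Over the alternatives Rny1 ranged from 1.01 to 4.57, passing in 16 of 22, Rn7s2 from 0.55 to 2.96 and Cox5b-ps from 0.79 to 2.34, so that their places in this order are not fixed. Rpl21-ps15 stood at 0.31 and 0.67 without LEV and at 2.86 and 2.78 with LEV, with 41.1 and 37.3 CPM in the PT 1 m LEV libraries and 7.40 and 7.75 CPM in the PT 1 m libraries.

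In all, limma called 2537 genes, 917 higher and 1620 lower, with 4746 at an unadjusted p under 0.05. The split depended on the scaling: TMM gave 163 higher and 147 lower, quantile normalization 862 and 833, DESeq2 528 and 290, and a fit with the trend on GC content and length removed 858 and 742. Of the called genes, 87.5% had the same sign in the difference between the naive library and the 2 m libraries, which were not used in this fit. A batch shared by the naive and 1 m libraries could give this too, so it does not bear out an effect of time. On simulated data, which held no batches, 27.4% of the calls of this fit were unchanged genes. Without the filter on low values limma called 24 genes. Without PT 1 m infarcted it called 1061 genes and without PT 7 d LEV non-infarcted 1280. Without both PT 1 m infarcted and PT 1 m LEV non-infarcted, the 2 libraries lowest in choroid plexus genes, it called 1770.

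The fourth and the fifth tests asked whether the difference between sides itself changed with time or with LEV. Between 1 m and 7 d the smallest p belonged to the histone genes H3c3 and H2ac5-ps, which held the same reads (log2 -2.22, SE 0.33), then to Lgals1, a galectin (-0.89), Cyba, a subunit of the phagocyte oxidase (-0.90), and Vim (-0.90). These were named after their values were seen, and none passed (adjusted p = 0.506). With LEV the leading genes, also named after their values were seen, were Slc13a4, a sulfate transporter (2.16, SE 0.23, adjusted p = 0.0815), Bmp6 (1.47), the growth factor Igf2 (1.93), Slc6a12 (2.36), the prostaglandin enzyme Ptgds (2.71) and Aldh1a2 (2.05). Ptgds stood at 7348 CPM in PT 7 d LEV infarcted and 1443 CPM in PT 7 d LEV non-infarcted. At 1 m it stood at 1523 CPM (infarcted) and 4027 CPM (other side) without LEV, and at 2261 and 1262 CPM with LEV. PT 7 d LEV infarcted also stood apart in the list of pericytes, smooth muscle and meningeal fibroblasts, which holds Igf2. Its centred median there was 0.73 against -0.18, -0.18 and -0.31 in the other 7 d libraries. At 1 m the list stood at -0.29 (infarcted) and 0.15 (other side) without LEV, and at -0.24 and -0.56 with LEV. Whether uneven amounts of such tissue lie behind the leading genes was not tested. Limma called 0 genes in both tests, with 872 and 816 at an unadjusted p under 0.05 where 803 would fall by chance. Without PT 7 d, PT 7 d LEV, PT 1 m or PT 1 m LEV in turn, the time test called 80, 167, 21 and 51 genes and the LEV test 311, 0, 390 and 0. In those fits 1 condition stood alone and was assumed to vary like the others.

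The remaining comparisons set each condition beside the single naive library, with no test. Across all tested genes the naive minus 2 m change had r = 0.507 with the 1 m minus 7 d change. A batch that parts the naive and 1 m libraries from the 7 d and 2 m libraries may thus enter the 7 d and 2 m comparisons. It cannot be told apart from PT there. A gene was counted when it differed by a log2 of 1 or more in the same direction on both sides. In PT 7 d, 38 genes were higher and 123 lower than naive. Leaving out clone names and identifiers, the 10 highest began with the small nucleolar RNA gene Snord32a (8.86 CPM in naive, 31.9 and 31.8 CPM in PT 7 d), Bloc1s2-ps and a second entry named Atp5o. Then came Snord33 and Snord34, which held the same reads, Snord35a, Rnu73b and Snord96a. Rims4, of the active zone of synapses, went from 2.71 to 8.40 and 8.85 CPM, and the carboxylase subunit gene Pccb from 1.57 to 5.49 and 6.91 CPM. The lowest were Rny1, Cacna1d (73.6 CPM in naive, 15.0 and 14.9 CPM in PT 7 d), Git1, a signalling scaffold (337 to 63.4 and 74.5 CPM), Mosmo, Stxbp3, Septin3, Dyrk2, Clk2, Plin4 and Tada2b. The bounds that counting error allows (exact Poisson, 95%) were 327 to 346 CPM for naive Git1 and 59.7 to 67.2 CPM for PT 7 d infarcted, and they cover counting error only. Rny1 had 0 reads in PT 7 d infarcted, which allows up to 0.171 CPM at 3 reads, against 11.5 CPM in naive.

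Beside random lists of like expression, the medians against naive in PT 7 d lay at percentile 100 for activated microglia (0.99), microglia (0.72), interferon (0.48) and heat shock genes (0.47), and at 99.96 for astrocyte genes (0.38). These medians average both sides. On the infarcted and the non-infarcted side they were 1.76 and 0.20 for activated microglia, 1.27 and 0.14 for microglia, 0.87 and 0.18 for interferon, 0.58 and 0.09 for astrocyte and 0.48 and 0.46 for heat shock genes. Hspa5 differed from naive by 0.59 and 0.57 and Hspa8 by 0.62 and 0.65 on the 2 sides. GABA synthesis and transport genes lay at percentile 0.06 (median -0.27), with Slc6a11 at -1.13 and -0.73. The GABA-A list was near the middle (0.00, percentile 35.28). With LEV at 7 d 34 genes were higher and 114 lower than naive, and the medians were 0.79 on the infarcted and -0.03 on the other side for activated microglia, 0.63 and 0.12 for microglia, 0.32 and 0.29 for heat shock and -0.10 and -0.07 for GABA synthesis genes.

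In PT 1 m, 1 gene was higher than naive and 41 lower. The lowest were Plin4, a lipid droplet protein, Cdkn1a, the cell cycle inhibitor p21, and Cdr2, beside the choroid plexus genes Ttr, Clic6, Folr1, Calml4, Mfrp, Prlr and Steap1. Plin4 went from 26.4 to 4.26 and 6.31 CPM. Glucocorticoid response genes had a median of -0.51 and choroid plexus genes of -1.93 (-2.54 infarcted, -1.14 non-infarcted), both at percentile 0, and ependyma genes were at -0.49. GABA-A subunits were at 0.10 (percentile 97.8). With LEV at 1 m 38 genes were higher and 32 lower (with quantile scaling 68.7% of the counted genes were higher in place of 54.3%), and immediate early genes lay at percentile 100 (0.26).

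In PT 2 m after withdrawal, 81 genes were higher and 262 lower than naive. Higher were Selenop, a plasma selenium carrier (115 to 383 and 418 CPM), the chemokine gene Ccl2 (0.857 to 4.91 and 7.24 CPM), the matrix genes Bgn and Col3a1, Pdpn, Anxa1, Clip3, Setdb1, Rims4 and Pccb. Lower were Rny1, Clk2, Hbb-bs, Hbb-bt, Git1 (70.4 and 72.1 CPM), Sap30l, Dyrk2, Septin3, Plin4 and Cacna1d. Lists of meninges and vessel walls (0.55; 0.94 infarcted, 0.48 non-infarcted), endothelium (0.58), myelin (0.53) and astrocytes (0.63) lay at percentile 100, GABA-A subunits at 97.75 (0.29), and blood genes at 0 (-1.36).

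For each condition the same count was made with each of the other 8 PT libraries in place of naive. It gave a median (range) of 108.5 (7 to 261) genes for PT 7 d, where naive gave 161, and 119 (14 to 247) for PT 7 d LEV, where naive gave 148. It gave 110 (41 to 180) for PT 1 m, 275 (53 to 648) for PT 1 m LEV and 135 (92 to 699) for PT 2 m, where naive gave 42, 70 and 343. The 5 naive counts lay inside these ranges.

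Withdrawal was set beside LEV at 1 m, where time and drug changed together. A batch that may part the 1 m from the 2 m libraries would change with them, and these cannot be told apart here. The sample labels give 2 weeks of withdrawal and the series text gives 1 week. Between them 192 genes were higher after withdrawal and 285 lower, or 111 and 403 with TMM scaling. Higher were the choroid plexus genes Kcnj13, Enpp2 and Aqp1, Selenop, Pdpn, Rims4, Clip3, Pccb, Id4 and Cd74, an antigen presentation gene. Lower were ribosomal pseudogenes (Rpl30-ps10, Rpl21-ps15, Rps12-ps4, Rpl22-ps1, Rpl39-ps, Rpl9-ps6), Rps21, H4c9, Pfdn2 and Mt2, which went from 1007 and 897 CPM to 185 and 128 CPM. Gabrg1 stood at 15.0 and 16.5 CPM with LEV at 1 m and at 31.2 and 28.8 CPM after withdrawal.

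The series title asks about a return to normal with LEV, so the PT change from naive on 1 side was set against the LEV change on the opposite side, which shares no library. A return would give a negative correlation, but if both sides came from the same animals, PT enters both changes with opposite sign and draws r below 0 without a return. Across the 16057 genes, which are not independent, Pearson's r was 0.03 (Spearman's rho -0.0005) for the infarcted and -0.21 (-0.22) for the non-infarcted PT change at 7 d, and 0.09 (-0.02) and -0.15 (-0.08) at 1 m. The sign of r differed between the pairings, while the 4 values of rho were below 0.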

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

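The tests of shared batches, of GC content and length, of time, of choroid plexus tissue, of neighbouring tissue, of 1 factor for all glial genes and of LEV in this part were chosen only after the result was seen, while the counts over other splits of the libraries were planned.

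In 2 cases 1 of the 5 differences between sides lay far from the other 4. Lgals3bp stood at 0.373 in PT 1 m, where the other pairs lay between 0.631 and 0.694, and Tgfbr2 at 0.0955 in PT 1 m, where the others lay between 0.396 and 0.492. Chance picks about 1 in 20 groups, which is 3.1 of the 62 tested.

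Some differences had opposite signs at 7 d and at 1 m in every pair. For the lists, and for LEV, the difference between time points was not tested. For the difference between sides (7 d, then 1 m), voltage-gated channels stood at -0.0251 and 0.0422, endothelium at 0.298 and -0.201, blood cells at 0.469 and -0.254, dentate granule cells at -0.0918 and 0.0945, neurogenesis at -0.0481 and 0.103, and Gabrg1 at 0.114 and -0.0953, which did not pass the limma test of side differences by time (adjusted p = 0.895). These were 6 of 62, where chance gives 7.8. For LEV, immediate early genes stood at -0.0824 and 0.309, interferon response at 0.0702 and -0.221, and myelinating oligodendrocytes at -0.206 and 0.0731. Blood cells stood at -0.637 and 0.065, neighbouring tissue at 0.159 and -0.0782, CA1 cells at -0.0481 and 0.185, ependyma at -0.0981 and 0.101, Gabra3 at 0.183 and -0.136, and Gabra4 at 0.125 and -0.0865. These were 9 of 63, where chance gives 7.9.

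The 1 m and 7 d libraries differed in 2537 genes. A time effect that lasts to 2 m would not by itself account for these calls. Over the called genes, in the direction of the call, the change from PT 7 d LEV to 2 m was -0.0616 of that to PT 1 m LEV (medians -0.04 and 0.62). A lasting effect is not excluded by this share. The genes were picked by the same 7 d and 1 m libraries, and a batch shared by 7 d and 2 m libraries would lower the share either way. A batch shared by the naive and 1 m libraries, and another by the 7 d and 2 m libraries, may lie behind much of the difference. Across all tested genes, which are not independent replicates, the 1 m minus 7 d change had r = 0.507 (rho 0.514) with the naive minus 2 m change, from other libraries. Removal of a trend on GC content and length left 0.593 of the calls, between the bounds written down for and against it before that share was computed. A change that came at 1 m and was gone by 2 m, animals' age, or LEV withdrawal stay open, and the labels name no batch.

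Choroid plexus genes were lower at 1 m. All 12 members of the list moved with LEV at 1 m in opposite directions on the 2 sides, a value that uneven amounts of choroid plexus tissue taken along in dissection could give. Of the 2 m libraries, 1 of 2 lay below the lowest 7 d library in the list median, so that a lasting time effect cannot be told apart from uneven tissue with 2 libraries. Both could act together.

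The glial difference between sides at 7 d was smaller with LEV. Neighbouring tissue that carries the markers of neocortex, thalamus and striatum is argued against in the PT 7 d infarcted library. The side difference of these markers was -0.0834 in PT 7 d minus PT 7 d LEV. The 95% interval of -0.263 to 0.172 resamples list members only, not libraries. The bound against such tissue was reworded after this value was seen, and the value met the earlier bound too. PT 7 d LEV infarcted had a centred list median of 0.218, against 0.008 in PT 7 d infarcted. The list mixes markers of these regions, so its median can miss tissue of a single region such as neocortex. Infarct tissue that had lost these markers would not raise the list either. Neighbouring tissue is therefore not excluded. The share of the excess left with LEV was 3.52 times as high for astrocyte genes (0.818, interval 0.288 to 1.64) as for activated microglia genes (0.232, 0.0947 to 0.65), and 1 factor for all glial genes stays open, since the overlap met the bound written for it but the intervals are wide. PT 7 d LEV infarcted also stood apart in pericyte and meningeal genes (centred median 0.73, against -0.18, -0.18 and -0.31 in the other 7 d libraries), and its share of other tissue was not tested as an explanation. For LEV itself, the side difference of activated microglia genes at 1 m was 0.216 higher with LEV, and with 1 library per side and condition the drug cannot be told apart from differences between animals or infarct sizes.

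Other splits of the same libraries were counted. For side, with a real count of 0 called genes, all 100 splits reach it by construction (highest other 50), so this count decides nothing. Of the 100 splits 7, the real one among them, gave as many genes at an unadjusted p under 0.05 as the real 1221 (highest other 1332). Unlike the real contrast, these splits did not keep 1 side of each condition in each group. This count therefore cannot exclude chance and is no close measure of it. For LEV, 4 of 33 splits of the 8 libraries, the real one among them, called as many genes as the real 1 (highest other 3), so chance is not excluded. For 1 m against 7 d, 1 of 33 splits, the real one, called as many genes as the real 4991 (highest other 1), so chance is excluded only where both sides of a condition are independent. Nearly all other splits parted the sides of a condition, and if sides share animals the 4 conditions make too few splits to exclude chance. A batch along the same split is not excluded either.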

How the results depend on the processing

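The removal of a GC and length trend, the fits without PT 1 m infarcted and PT 1 m LEV non-infarcted together and the list tests without the PT 7 d pair were chosen after seeing the data. The cause of the shifts below was not tested unless stated. The side count of 0 was 0 under 9 alternatives that changed the processing (no block included), 14 with DESeq2, and 0 to 50 without 1 condition in turn (50 without PT 1 m). The LEV count of 3 was 12 with a pseudocount of 0.25, and 0 with a pseudocount of 5, no filter, TMM, quantile scaling or no trend. It was 7 with edgeR, 1 with DESeq2, 1 with 8 libraries as independent, 1 with duplicateCorrelation, 6 on the infarcted and 52 on the non-infarcted side alone, and 1 without the 2 libraries low in choroid plexus genes. Without 1 library in turn it was 0 to 62 (62 without PT 7 d infarcted, 7 without PT 7 d LEV infarcted, 0 without PT 7 d non-infarcted, PT 7 d LEV non-infarcted, PT 1 m infarcted or PT 1 m non-infarcted). The 1 m against 7 d count of 2537 was 24 with no filter, 310 with TMM, 818 with DESeq2, 4991 with 8 libraries as independent, 4173 with duplicateCorrelation and 1600 with the GC and length trend removed. The 8 libraries leave more residual degrees of freedom by construction. Without 1 library in turn it was 1061 (PT 1 m infarcted) to 2392, with 1280 without PT 7 d LEV non-infarcted, and it stayed between 1695 and 2773 under 9 others. The counts of 0 for the side difference became 21 to 167 by time and 0 to 390 by LEV without 1 condition in turn (311 without PT 7 d, 390 without PT 1 m). Against naive, a pseudocount of 5, which shrinks changes at low CPM by construction, gave 84 genes for PT 7 d, 87 for PT 7 d LEV, 19 for PT 1 m, 18 for PT 1 m LEV, 201 for PT 2 m, and 235 for withdrawal against PT 1 m LEV. A pseudocount of 0.25 gave 85 for PT 1 m and 124 for PT 1 m LEV. On the same side, where the PT library is shared and pulls r down by construction, the return had r = -0.502 (7 d, infarcted), -0.467 (1 m, infarcted) and -0.295 (1 m, non-infarcted). Of 31 list calls 0 passed with an estimated correlation and 0 with fry. For LEV and time this decides nothing, since both called 0 of 2 moved lists there on simulated data, against 2 of 2 for side. Some settings also added calls. With TMM 12 lists passed for side, of which 9 had passed in the main fit, and 11 for LEV, of which 10 had. Without the PT 7 d pair 10 passed for side (8 of them in the main fit too). Without the 2 libraries low in choroid plexus genes 8 passed for LEV (6 of them in the main fit too). Ttr and Slc6a13 reversed with LEV on the non-infarcted side alone (-1.88 and -0.81). Of the named genes' alternatives, 1435 of 1622 stood on the same side of the threshold for time (170 weaker, 17 stronger), 972 of 993 for side (21 stronger) and 1591 of 1644 for LEV (26 weaker, 25 stronger). Depth limits values under 0.134 to 0.224 CPM.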

Other observations

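The list tests in this part were planned, while the single genes and the counts by type of gene were chosen after the result was seen. Whether a list passed is given for the main fits. Synaptic and excitability lists passed in none of the 3 tested contrasts (medians for side, LEV, then 1 m against 7 d, with the camera adjusted p). SV2 and vesicle release genes stood at -0.02 (0.112), -0.01 (0.488; 0.02 with TMM) and -0.19 (0.271), over time with 10 of 18 members lower in 4 of 4 pairs and 4 called lower. Voltage-gated channels stood at 0.00 (0.123), 0.06 (0.0959) and 0.11 (0.0706), ionotropic glutamate receptors at -0.01 (0.336), 0.01 (0.536) and 0.16 (0.127), and metabotropic receptors with glutamate transport at 0.01 (0.749; -0.02 with TMM), 0.05 (0.488) and -0.02 (0.271; 0.03 with TMM). At 1 m against 7 d single members were called all the same. Slc17a7, the vesicular glutamate transporter of excitatory neurons, rose by 0.91, the potassium channel gene Kcnq3 by 0.65, and Syn1, a synapsin, by 0.77. Stx1a, a syntaxin, fell by 0.67, Cplx2, a complexin, by 0.60 and the sodium channel gene Scn1a by 0.53.

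The other lists that passed in none of the 3 contrasts were oligodendrocyte precursors, at 0.10 (0.183), -0.14 (0.0683) and -0.27 (0.168), endothelium, at 0.06 (0.183), -0.11 (0.0959) and -0.35 (0.271), and pericytes with meningeal fibroblasts, at 0.13 (0.0587), 0.05 (0.967) and -0.26 (0.194). CA2 with CA3 cells stood at -0.02 (0.257), -0.03 (0.696) and -0.04 (0.559; 0.01 with TMM), neurogenesis at 0.04 (0.831), 0.07 (0.508) and 0.03 (0.515), and mitochondrial genes at -0.01 (0.183), 0.04 (0.17) and 0.00 (0.231). The sign of the median and of the test differed for GABA synthesis genes between sides (0.00, test down), for metabotropic receptors between sides (down) and over time (up), for CA2 with CA3 with LEV and over time (up), for pericytes with LEV (down) and for immediate early genes over time (-0.10, up).

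In the difference between 1 m and 7 d calls fell on several types of gene. Of 189 processed pseudogenes 54 were called (36 higher, 18 lower), of 128 small nucleolar RNA genes 49 (17 higher, 32 lower), and of 13672 protein-coding genes 2213 (743 higher, 1470 lower). The median GC content was 52.1% for genes called higher and 48.4% for genes called lower.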
